A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

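Poly(A)-selected RNA was measured by sequencing in Saccharomyces cerevisiae, budding yeast, in 17 libraries. The labels give 1 strain for all of them, in which the exonuclease Xrn1 carries an auxin-inducible degron and the plant receptor OsTIR1 is expressed. Cells in rich medium were treated with 500 µM auxin for 30 min (Xrn1-AID) or left without auxin (Xrn1-WT), and the labels name no solvent control. Both arms were sampled before and 10 and 30 min after addition of NaCl to 0.4 M. Each group had 3 libraries, except Xrn1-AID at 30 min, which had 2. The labels do not say whether replicates were separate cultures, so the p-values may measure technical spread in part.

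The deposited values were raw read counts per gene, per the submitters' processing notes from 50 base single-end reads of a stranded mRNA kit on a HiSeq 2500, with TopHat2 2.1.0, featureCounts 1.5.1, DESeq2 1.22.2 and the sacCer3 build named. The notes do not state the role of each tool, the strand setting of the counting, the treatment of reads with several alignments or the annotation used. Values of near-identical genes and of genes that overlap on opposite strands are therefore uncertain. The table held 7126 features, of which 6048 (84.87%) matched a RefSeq locus tag, among them 6007 of 6021 protein-coding genes. Gene coordinates below are those of the coding region in that annotation of sacCer3.

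Total counts per library ranged from 13.9 to 30.4 M. A count of 0 in a library allowed up to 3 counts, or between 0.104 and 0.279 counts per M counts (CPM) depending on the library. Ribosomal RNA took between 0.00181% and 0.094% of the counts and small nuclear and nucleolar RNA between 0.00881% and 0.107%. Floors cover counting error only, since the reads carried no molecular identifiers, and bootstrap intervals cover the spread between genes.

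Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 6195 genes, TMM factors scaled the libraries, and a quasi-likelihood model (glmQLFit with robust estimation) held 1 mean for each of the 6 groups. The 12 contrasts were 30 and 10 min against 0 min and 30 against 10 min in each arm, Xrn1-AID against Xrn1-WT at each time, and the 3 differences between the arms' responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, with no fold threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM are given as mean ± SD of the TMM-scaled libraries of a group.

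The 22 gene lists were written from textbook knowledge and tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Their p-values were adjusted over all lists and contrasts. The same test with a correlation estimated from the residuals was an alternative, and fry, which asks whether a list's genes move on balance in 1 direction, was another. A list count is over all tested genes, with the count adjusted over the list alone beside it.

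Genes were named by a fixed rule: XRN1, a panel of 16 genes, the 6 genes per direction with the largest change among those called, with a mean of at least 10 CPM and with no overlap between the libraries of the compared groups, and the 4 called members of each list with the largest changes. For the differences between responses the rule held without the overlap condition. Genes named outside it (the selection markers, the nonsense-mediated decay targets picked as examples from a longer list, and the members of 4 later gene groups) were chosen after their values were seen. The lists, contrasts, tests, naming rule and the alternatives named next were fixed before the data were examined.

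The size of the NaCl response in the arms was compared across genes by a standardised major axis slope with a bootstrap interval (1000 resamples of genes, 95%), and genes are not independent replicates. Alternatives were DESeq2 size factors, library size alone, no filter and a filter at a mean of 10 CPM, the Wald test of DESeq2 1.42.0, replicate blocks from the numbers in the labels, a fit of the compared groups alone, glmTreat at 1.5-fold, and leaving out each replicate. DESeq2 gave no adjusted p for 6 genes in each of 9 contrasts and for 247, 367 and 247 genes in the differences between responses. Alternatives chosen after the data were seen were a correction for GC content and coding length per library (natural splines with 5 degrees of freedom, 93.1% of the tested genes) and omission of the 2 libraries that deviated most from their group.

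The procedure was tested on counts simulated from means and dispersions of the data, with known changes in 200 genes only. For 10 against 0 min in Xrn1-WT it recovered 14.9%, 80.6% and 100% of the changes of 1.5-fold, 2-fold and 4-fold. The shares were 7.5%, 67.2% and 98.5% for the arms at 30 min, and 7.5%, 35.8% and 95.5% for the difference between the 10 min responses. False calls were 5 of 135, 8 of 123 and 7 of 99. These rates may differ where more genes change, as with NaCl. A list raised 1.3-fold was called (adjusted p = 4.26e-23), and 1 other of 21 lists passed. A simulated GC trend gave 754 calls between the arms without the correction and 0 with it. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9.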

Results

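Budding yeast with a degron on Xrn1, the cytoplasmic 5' to 3' exonuclease of mRNA decay, were given 0.4 M NaCl for 0, 10 or 30 min, with the degron left alone (Xrn1-WT) or triggered by auxin for 30 min (Xrn1-AID). Libraries are named by arm, minutes and replicate number of the title, as in WT 0 replicate 3. Depth (M counts) was 16.5, 17.8 and 30.4 for WT 0, 17.5, 18.2 and 17.04 for WT 10, and 17.4, 16.6 and 13.9 for WT 30. For Xrn1-AID it was 22.7, 19.5 and 18.7 at 0 min, 19.2, 19.8 and 19.5 at 10 min, and 16.7 and 21.2 at 30 min, the only group with n = 2. Changes are log2 fold changes ± SE, and 6195 genes were tested.

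XRN1 (YGL173C) mRNA (chromosome VII, 175527 to 180113) stood at 25.04 ± 13.2, 35.6 ± 13.3 and 40.5 ± 6.70 CPM in Xrn1-WT at 0, 10 and 30 min. In Xrn1-AID it stood at 58.5 ± 8.42, 50.9 ± 1.70 and 52.1 ± 25.4 CPM. The gene was higher in Xrn1-AID at 0 min (1.23 ± 0.35, adjusted p = 0.0153, adjusted p = 0.0862 with library size alone and 0.0507 with only the compared groups), but did not pass at 10 min (0.51 ± 0.35, adjusted p = 0.28) or 30 min (0.36 ± 0.38, adjusted p = 0.531). The degron acts on the protein, so these levels do not show whether Xrn1 was lost. Per the submitters' description less than 10% of the protein was left after auxin.

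Levels of some RNAs without a long poly(A) tail follow. The U2 spliceosomal RNA LSR1 stood at 18.2 ± 10.96, 64.6 ± 49.9 and 55.5 ± 82.3 CPM in Xrn1-WT and at 3.5996 ± 1.37, 4.09 ± 0.838 and 7.43 ± 6.01 in Xrn1-AID. Mitochondrial reading frames, without the mitochondrial ribosomal RNAs, made up 0.000264% to 0.0044% of the counts in Xrn1-WT libraries and 4.4e-06% to 0.000359% in Xrn1-AID libraries. Among the 5 mitochondrially encoded genes tested, OLI1, a subunit of the ATP synthase ring, stood at 0.269, 1.27 and 0.43 CPM in Xrn1-WT and at 0 in all 8 Xrn1-AID libraries, whose floors were 0.104 to 0.195 CPM. COX1, a cytochrome oxidase subunit, stood at 0.242, 1.27 and 0.469 CPM against 0.017, 0 and 0.0503. The list of these genes was lower in Xrn1-AID at 10 min (adjusted p = 0.00271, adjusted p = 0.498 with an estimated correlation, 0.0687 after the GC and length correction) and did not pass at 0 min (adjusted p = 0.102) or 30 min (adjusted p = 0.0798). Small nuclear and nucleolar RNA had its largest shares in WT 30 replicate 3 (0.107%) and WT 10 replicate 2 (0.0572%).

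The first comparison asked which mRNAs changed after 10 min of NaCl in Xrn1-WT cells. STL1 (YDR536W), the glycerol importer of the plasma membrane (chromosome IV, 1508005 to 1509714), went from 7.27 ± 9.23 to 1898 ± 475 CPM (mean ± SD, n = 3), a log2 fold change of 8.05 ± 0.77 (adjusted p = 4.5e-07). Also raised were FMP48 (YGR052W, 7.94 ± 0.55), the catalase gene CTT1 (YGR088W, 6.83 ± 0.52, chromosome VII, 654634 to 656322), and MGA1 (YGR249W, 6.79 ± 0.44), PHM7 (YOL084W, 6.78 ± 0.49) and MPC3 (YGR243W, 6.77 ± 0.46). Without WT 0 replicate 1, which held 17.9 CPM of STL1 against 1.6 and 2.29 in the other replicates, STL1, FMP48, CTT1 and PHM7 changed by 9.92, 9.02, 7.85 and 7.78. The glycerol synthesis genes GPD1 (YDL022W, 6.37 ± 0.35) and GPP1 (YIL053W, 2.04 ± 0.21) and the sodium pump gene ENA1 (YDR040C, 3.69 ± 0.23), whose near-identical neighbours make its counts uncertain, rose too. The largest falls were in RRN11 (YML043C, -3.64 ± 0.27), an initiation factor of RNA polymerase I, the cell cycle inhibitor gene FAR1 (YJL157C, -3.13 ± 0.25), and RFU1 (YLR073C, -3.01 ± 0.20), HO (YDL227C, -2.82 ± 0.20), PHO84 (YML123C, -2.75 ± 0.26) and KAR1 (YNL188W, -2.73 ± 0.25). In total 2740 genes passed, 1218 higher and 1522 lower, 667 and 518 of them by more than 2-fold. With library size alone as the scaling the split was 586 and 2463, and the median of all genes moved to -0.503.

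27 of 28 Hog1 osmostress effectors rose and 0 fell (27 and 1 adjusted over the list alone). Their median was 3.74 (adjusted p = 7.1e-29, adjusted p = 0.0417 with an estimated correlation). 47 of 47 Msn2/Msn4 general stress genes rose and 0 fell (the same adjusted over the list alone), among them SPI1 (YER150W, 6.04 ± 0.57), TKL2 (YBR117C, 5.89 ± 0.49) and DDR2 (YOL052C-A, 5.88 ± 0.52, 7.17, 6.89 and 7.001 without WT 0 replicate 1). Their median was 3.43 (adjusted p = 2.79e-58, adjusted p = 0.0365 with an estimated correlation). Reserve carbohydrates followed: 15 of 18 trehalose and glycogen genes rose and 0 fell (16 and 0 adjusted over the list alone), with TSL1 (YML100W, 5.38 ± 0.29) and TPS2 (YDR074W, 5.02 ± 0.29) near the top. Their median was 2.40 (adjusted p = 2.41e-21, adjusted p = 0.0493 with an estimated correlation). Chaperones rose with HSP26 (YBR072W, 5.75 ± 0.42) and HSP42 (YDR171W, 5.27 ± 0.27) in front, as 22 of 27 Hsf1 chaperone genes rose and 1 fell (the same adjusted over the list alone). Their median was 1.37 (adjusted p = 3.25e-16, adjusted p = 0.0621 with an estimated correlation). 13 of 21 cell wall integrity genes rose and 0 fell (14 and 0 adjusted over the list alone), as in CWP1 (YKL096W, 3.47 ± 0.37) and YPS1 (YLR120C, 3.11 ± 0.28). Their median was 1.16 (adjusted p = 2.36e-06, adjusted p = 0.175 with an estimated correlation). Energy genes rose less: 22 of 37 oxidative phosphorylation genes rose and 0 fell (23 and 0 adjusted over the list alone) with QCR8 (YJL166W, 2.18 ± 0.22). Their median was 0.55 (adjusted p = 0.000487, adjusted p = 0.592 with an estimated correlation). Among pump genes such as TPO4 (YOR273C, 5.53 ± 0.29) and RSB1 (YOR049C, 3.09 ± 0.32), 8 of 17 pleiotropic drug resistance genes rose and 0 fell (the same adjusted over the list alone), but by library size alone the median was -0.06. Their median was 0.39 (adjusted p = 0.0145, adjusted p = 0.669 with an estimated correlation). 13 of 33 proteasome genes rose and 0 fell (the same adjusted over the list alone), but by library size alone the median was -0.23, and the proteasome's activator gene RPN4 (YDL020C, 1.79 ± 0.22) rose the most. Their median was 0.21 (adjusted p = 0.0394, adjusted p = 0.695 with an estimated correlation).

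At 10 min 99 of 123 ribosome biogenesis genes fell and 1 rose (105 and 1 adjusted over the list alone), among them ALB1 (YJL122W, -2.56 ± 0.22), SPB1 (YCL054W, -2.53 ± 0.29) and RRP9 (YPR137W, -2.29 ± 0.25). Their median was -0.97 (adjusted p = 4.56e-20, adjusted p = 0.239 with an estimated correlation). 12 of 19 RNA polymerase I and III genes fell and 0 rose (12 and 1 adjusted over the list alone), such as RPC19 (YNL113W, -1.90 ± 0.20) and RPC31 (YNL151C, -1.51 ± 0.16). Their median was -0.76 (adjusted p = 0.000358, adjusted p = 0.175 with an estimated correlation). 41 of 69 mitochondrial ribosomal protein genes fell and 2 rose (42 and 2 adjusted over the list alone), for example MRPS28 (YDR337W, -1.26 ± 0.16) and MRPL33 (YMR286W, -1.09 ± 0.19). Their median was -0.55 (adjusted p = 0.000183, adjusted p = 0.695 with an estimated correlation). Cytosolic ribosomal protein genes did not pass as a list: 7 of 138 fell and 0 rose (4 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.785). The mRNA decay list did not pass, with DCS1 (YLR270W, 2.65 ± 0.17) and EDC2 (YER035W, 2.50 ± 0.26) up and VTS1 (YOR359W, -2.64 ± 0.20) down, and 13 of 46 mRNA decay factor genes fell and 5 rose (the same adjusted over the list alone). Their median was -0.20 (adjusted p = 0.342, adjusted p = 0.768 with an estimated correlation). For the small last list, 3 of 13 markers of mating type alpha and meiosis rose and 1 fell (the same adjusted over the list alone), with IME2 (YJL106W, 2.54 ± 0.28) and SPS1 (YDR523C, 1.79 ± 0.27) raised and SPS4 (YOR313C, -1.80 ± 0.30) lowered. Their median was 0.45 (adjusted p = 0.578, adjusted p = 0.858 with an estimated correlation). In all 9 lists rose, 3 fell and 10 did not pass (adjusted p from 0.0976 to 0.785). Calls that ended with 1 library left out or with the GC and length correction were the proteasome genes (adjusted p = 0.0576 without WT 0 replicate 3, 0.112 and 0.0634 without WT 10 replicates 2 and 3, 0.0756 after the GC and length correction).

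After 30 min of NaCl in Xrn1-WT the question was the same. The transketolase gene TKL2 (7.72 ± 0.53, chromosome II, 474392 to 476437) led, from 5.56 ± 4.93 to 1161 ± 162 CPM (n = 3 and 3, adjusted p = 2.86e-09), followed by YNL194C (7.21 ± 0.50), CTT1 (6.91 ± 0.52), PHM7 (6.91 ± 0.49), DDR2 (6.89 ± 0.54) and STL1 (6.85 ± 0.73). Without WT 0 replicate 1 these 6 changed by 8.71, 8.28, 7.92, 7.91, 8.01 and 8.72. The adenine deaminase gene AAH1 (YNL141W, -6.08 ± 0.30, chromosome XIV, 359596 to 360639) fell furthest, from 198 ± 55.1 to 2.91 ± 0.424 CPM, with the acid phosphatase genes PHO12 (YHR215W, -5.68 ± 0.19) and PHO11 (YAR071W, -5.62 ± 0.16), a near-identical pair whose counts are uncertain, and HO (-5.36 ± 0.23), UTP23 (YOR004W, -5.04 ± 0.19) and SFG1 (YOR315W, -4.85 ± 0.48). Hog1 targets stayed up, with GPD1 (5.40 ± 0.33) and ENA1 (2.72 ± 0.23), while RPL3 (YOR063W, -2.71 ± 0.40), NOP1 (YDL014W, -2.61 ± 0.17) and RPA190 (YOR341W, -3.87 ± 0.26) had fallen (RPL3 by 1.92 without WT 0 replicate 3). A total of 3506 genes passed, 1801 higher and 1705 lower, 1011 and 1053 of them by more than 2-fold. Library size alone gave 2410 and 997 and moved the median of all genes to 0.429.

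Stress lists stayed raised at 30 min: 26 of 28 Hog1 osmostress effectors rose and 1 fell (the same adjusted over the list alone), and 46 of 47 Msn2/Msn4 general stress genes rose and 0 fell (the same adjusted over the list alone). Their medians were 5.28 (adjusted p = 1.98e-19, adjusted p = 0.0548 with an estimated correlation) and 5.04 (adjusted p = 2.78e-41, adjusted p = 0.0493 with an estimated correlation). 17 of 18 trehalose and glycogen genes rose and 0 fell (the same adjusted over the list alone), with PGM2 (YMR105C, 5.73 ± 0.32) and GPH1 (YPR160W, 5.09 ± 0.33) prominent. Their median was 3.73 (adjusted p = 1.71e-18, adjusted p = 0.0496 with an estimated correlation). 14 of 27 Hsf1 chaperone genes rose and 5 fell (the same adjusted over the list alone), led by HSP26 (6.03 ± 0.43) and SSA4 (YER103W, 5.03 ± 0.26). Their median was 0.53 (adjusted p = 0.00602, adjusted p = 0.657 with an estimated correlation). 30 of 33 proteasome genes rose and 0 fell (the same adjusted over the list alone), for example PUP1 (YOR157C, 1.15 ± 0.19) and PRE4 (YFR050C, 1.14 ± 0.14). Their median was 0.74 (adjusted p = 0.000615, adjusted p = 0.498 with an estimated correlation). Respiratory genes such as NDE2 (YDL085W, 4.48 ± 0.28) and NDI1 (YML120C, 2.47 ± 0.35) rose, and of the whole group 19 of 37 oxidative phosphorylation genes rose and 0 fell (the same adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0155, adjusted p = 0.695 with an estimated correlation).

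Genes of the cytosolic ribosome, a family with near-identical pairs, fell by 30 min: 138 of 138 cytosolic ribosomal protein genes fell and 0 rose (the same adjusted over the list alone), for example RPS31 (YLR167W, -2.96 ± 0.45), which fell by 2.20 without WT 0 replicate 3. Their median was -2.41 (adjusted p = 2.29e-27, adjusted p = 0.502 with an estimated correlation). 121 of 123 ribosome biogenesis genes fell and 1 rose (the same adjusted over the list alone), with NOP7 (YGR103W, -4.74 ± 0.21), ENP2 (YGR145W, -4.66 ± 0.20) and DBP2 (YNL112W, -4.64 ± 0.24) far down. Their median was -2.98 (adjusted p = 1.09e-68, adjusted p = 0.0365 with an estimated correlation). 18 of 19 RNA polymerase I and III genes fell and 0 rose (the same adjusted over the list alone), among them RPA135 (YPR010C, -3.98 ± 0.22) and RPA43 (YOR340C, -3.62 ± 0.22). Their median was -2.06 (adjusted p = 2.36e-12, adjusted p = 0.0365 with an estimated correlation). Amino acid pathways fell through MET17 (YLR303W, -3.49 ± 0.20), MET6 (YER091C, -3.25 ± 0.20) and ARG1 (YOL058W, -3.23 ± 0.23), and 48 of 57 amino acid biosynthesis genes fell and 0 rose (49 and 0 adjusted over the list alone). Their median was -1.24 (adjusted p = 4.32e-12, adjusted p = 0.0496 with an estimated correlation). 20 of 29 cell cycle genes fell and 3 rose (21 and 3 adjusted over the list alone), as in POL1 (YNL102W, -2.33 ± 0.20), ALK1 (YGL021W, -2.27 ± 0.29) and CLB2 (YPR119W, -1.92 ± 0.47, CLB2 -1.18 without WT 0 replicate 2). Their median was -1.04 (adjusted p = 0.00471, adjusted p = 0.695 with an estimated correlation). In all 6 lists rose, 5 fell and 11 did not pass (adjusted p from 0.0728 to 0.993). With left-out libraries, DESeq2 size factors or the GC and length correction 1 call ended, that of the oxidative phosphorylation genes (adjusted p = 0.0603 after the GC and length correction).

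The 10 min comparison in Xrn1-AID asked which mRNAs changed in auxin-treated cells. STL1 rose from 0.874 ± 0.434 to 2484 ± 108 CPM (n = 3 and 3), a change of 11.49 ± 0.91 (adjusted p = 4.64e-08). It was followed by FMP48 (9.24 ± 0.58), YNL194C (9.17 ± 0.56), the membrane protector gene HSP12 (YFL014W, 8.89 ± 0.84), RTC3 (YHR087W, 8.46 ± 0.84) and CTT1 (8.32 ± 0.56). Lowest were PHO84 (-2.74 ± 0.26), VTS1 (-2.72 ± 0.20), RRN11 (-2.71 ± 0.25), HO (-2.39 ± 0.20), TIR4 (YOR009W, -2.36 ± 0.21) and RFU1 (-2.32 ± 0.19). In total 2202 genes passed, 1174 higher and 1028 lower, 604 and 316 by more than 2-fold. By library size alone the split was 608 and 1553 and the median of all genes -0.357.

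Osmostress and general stress genes rose together here: 27 of 28 Hog1 osmostress effectors rose and 0 fell (the same adjusted over the list alone), and 46 of 47 Msn2/Msn4 general stress genes rose and 0 fell (the same adjusted over the list alone). Their medians were 4.07 (adjusted p = 6.04e-38, adjusted p = 0.0365 with an estimated correlation) and 3.96 (adjusted p = 6.7e-73, adjusted p = 0.0365 with an estimated correlation). 17 of 18 trehalose and glycogen genes rose and 0 fell (18 and 0 adjusted over the list alone). Their median was 2.94 (adjusted p = 1.57e-25, adjusted p = 0.0365 with an estimated correlation). 18 of 27 Hsf1 chaperone genes rose and 1 fell (the same adjusted over the list alone), with HSP26 (6.18 ± 0.43) and HSP104 (YLL026W, 3.19 ± 0.20). Their median was 1.02 (adjusted p = 4.8e-09, adjusted p = 0.171 with an estimated correlation). Core histone genes, each with a near-identical copy, were raised in this arm through HTA1 (YDR225W, 1.09 ± 0.30) and HHT1 (YBR010W, 0.94 ± 0.18), as 6 of 8 core histone genes rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.90 (adjusted p = 0.0358, adjusted p = 0.695 with an estimated correlation). Down went DBP7 (YKR024C, -1.77 ± 0.21) and other biogenesis genes, where 78 of 123 ribosome biogenesis genes fell and 1 rose (85 and 1 adjusted over the list alone). Their median was -0.70 (adjusted p = 9.25e-16, adjusted p = 0.351 with an estimated correlation). Over all lists 8 lists rose, 2 fell and 12 did not pass (adjusted p from 0.094 to 0.992). Ended calls were those of the core histone genes (adjusted p = 0.0548 without AID 0 replicate 1, 0.0847 without AID 10 replicate 1, 0.112 after the GC and length correction).

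At 30 min in Xrn1-AID, with n = 3 and 2, HSP12 (chromosome VI, 107256 to 107585) rose from 12.6 ± 2.57 to 12544 ± 225 CPM, by 9.96 ± 0.89 (adjusted p = 1.06e-07). STL1 (9.00 ± 0.85), RTC3 (8.76 ± 0.87), DDR2 (8.71 ± 0.61), YNL194C (8.62 ± 0.57) and TKL2 (8.48 ± 0.56) came next. AAH1 fell by the most (-5.39 ± 0.34), then HO (-4.94 ± 0.27), INA1 (YLR413W, -4.93 ± 0.34), SFG1 (-4.57 ± 0.55), the RNA helicase gene DBP2 (-4.48 ± 0.29) and SYO1 (YDL063C, -4.41 ± 0.28). A total of 3334 genes passed, 1685 higher and 1649 lower. Library size alone gave 1951 and 978, with a median of all genes of 0.293.

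For the stress groups 26 of 28 Hog1 osmostress effectors rose and 1 fell (the same adjusted over the list alone), and 45 of 47 Msn2/Msn4 general stress genes rose and 0 fell (46 and 0 adjusted over the list alone). Their medians were 5.06 (adjusted p = 5.7e-22, adjusted p = 0.0621 with an estimated correlation) and 4.61 (adjusted p = 1.49e-46, adjusted p = 0.0473 with an estimated correlation). 17 of 18 trehalose and glycogen genes rose and 1 fell (the same adjusted over the list alone). Their median was 3.08 (adjusted p = 1.26e-16, adjusted p = 0.0496 with an estimated correlation). 28 of 33 proteasome genes rose and 0 fell (the same adjusted over the list alone), for example RPT2 (YDL007W, 1.10 ± 0.16) and PUP3 (YER094C, 1.09 ± 0.17). Their median was 0.80 (adjusted p = 2.77e-05, adjusted p = 0.33 with an estimated correlation). Ribosomal protein genes fell in this arm too: 125 of 138 cytosolic ribosomal protein genes fell and 0 rose (131 and 0 adjusted over the list alone). Their median was -1.42 (adjusted p = 1.05e-12, adjusted p = 0.695 with an estimated correlation). 121 of 123 ribosome biogenesis genes fell and 1 rose (the same adjusted over the list alone), as in SDA1 (YGR245C, -3.99 ± 0.21), RRP12 (YPL012W, -3.71 ± 0.35) and NSR1 (YGR159C, -3.68 ± 0.29). Their median was -2.31 (adjusted p = 5.41e-49, adjusted p = 0.0496 with an estimated correlation).

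Further lists fell at 30 min in Xrn1-AID. 46 of 57 amino acid biosynthesis genes fell and 0 rose (the same adjusted over the list alone). Their median was -1.18 (adjusted p = 4.73e-13, adjusted p = 0.0496 with an estimated correlation). Sterol genes fell through ERG25 (YGR060W, -3.13 ± 0.28), ERG11 (YHR007C, -3.10 ± 0.40) and ERG3 (YLR056W, -2.87 ± 0.20), as 14 of 28 ergosterol genes fell and 2 rose (the same adjusted over the list alone). Their median was -0.60 (adjusted p = 0.00119, adjusted p = 0.191 with an estimated correlation). 23 of 29 cell cycle genes fell and 2 rose (the same adjusted over the list alone), with CLB6 (YGR109C, -3.98 ± 0.32) and RNR1 (YER070W, -2.61 ± 0.26) lowest. Their median was -1.34 (adjusted p = 4.09e-05, adjusted p = 0.598 with an estimated correlation). 7 of 8 core histone genes fell and 0 rose (8 and 0 adjusted over the list alone), a call that ended at adjusted p = 0.0647 without AID 30 replicate 2. Their median was -1.11 (adjusted p = 0.0335, adjusted p = 0.695 with an estimated correlation). In all 5 lists rose, 8 fell and 9 did not pass (adjusted p from 0.0891 to 0.89).

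Between 10 and 30 min of NaCl the question was which mRNAs kept rising or turned. In Xrn1-WT the hydrophilin genes GRE1 (YPL223C, 4.66 ± 0.40) and SIP18 (YMR175W, 4.17 ± 0.45) rose further, GRE1 (chromosome XVI, 128632 to 129138) from 11.8 ± 2.04 to 298 ± 47.4 CPM (adjusted p = 9.56e-08, n = 3 and 3), with the mRNA decay factor gene TIS11 (YLR136C, 4.03 ± 0.28) and UIP4 (YPL186C, 3.99 ± 0.24), SPG4 (YMR107W, 3.96 ± 0.42) and YTP1 (YNL237W, 3.77 ± 0.21). AAH1 (-5.57 ± 0.29), PHO11 (-4.95 ± 0.16), PHO12 (-4.88 ± 0.19), DBP2 (-4.70 ± 0.25), the hypoxic repressor gene ROX1 (YPR065W, -4.54 ± 0.46) and HCA4 (YJL033W, -4.35 ± 0.19) fell the most. STL1 did not pass (-1.20 ± 0.57, adjusted p = 0.0852). In total 3488 genes passed, 1895 higher and 1593 lower, 799 and 1012 by more than 2-fold, and library size alone gave 3740 and 685 with a median of all genes of 0.94. 136 of 138 cytosolic ribosomal protein genes fell and 0 rose (the same adjusted over the list alone). Their median was -2.53 (adjusted p = 9.66e-41, adjusted p = 0.339 with an estimated correlation). 113 of 123 ribosome biogenesis genes fell and 2 rose (114 and 3 adjusted over the list alone). Their median was -1.87 (adjusted p = 2.17e-44, adjusted p = 0.0621 with an estimated correlation). 29 of 47 Msn2/Msn4 general stress genes rose and 4 fell (32 and 4 adjusted over the list alone), with DCS2 (YOR173W, 3.40 ± 0.32) and GPH1 (2.98 ± 0.30). Their median was 1.00 (adjusted p = 7.62e-05, adjusted p = 0.675 with an estimated correlation). Chaperone genes came back down, BTN2 (YGR142W, -3.07 ± 0.30) and HSP82 (YPL240C, -1.80 ± 0.19) among them: 21 of 27 Hsf1 chaperone genes fell and 4 rose (the same adjusted over the list alone). Their median was -0.94 (adjusted p = 0.00229, adjusted p = 0.606 with an estimated correlation).

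Metabolic lists fell over the same interval in Xrn1-WT, as 51 of 57 amino acid biosynthesis genes fell and 2 rose (52 and 2 adjusted over the list alone). Their median was -1.39 (adjusted p = 2.7e-18, adjusted p = 0.0365 with an estimated correlation). 11 of 21 cell wall integrity genes fell and 2 rose (12 and 2 adjusted over the list alone), but the median was 0.21 with library size alone, and the call ended at adjusted p = 0.0535 without WT 10 replicate 3. Their median was -0.58 (adjusted p = 0.0304, adjusted p = 0.631 with an estimated correlation).

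In Xrn1-AID (n = 3 and 2) GRE1 (4.83 ± 0.42), TIS11 (4.18 ± 0.29), SIP18 (3.88 ± 0.45), the siderophore mannoprotein gene FIT2 (YOR382W, 3.37 ± 0.37), YTP1 (3.34 ± 0.21) and PAI3 (YMR174C, 3.26 ± 0.34) rose the most between 10 and 30 min. ROX1 (-5.73 ± 0.58), the repressor gene NRG2 (YBR066C, -4.93 ± 0.23), AAH1 (-4.92 ± 0.34), DBP2 (-4.36 ± 0.29), MGA1 (-4.32 ± 0.44) and FRE4 (YNR060W, -4.22 ± 0.32) fell the most (ROX1 and MGA1 by 6.41 and 4.90 without AID 30 replicate 2). STL1 fell as well (-2.50 ± 0.70, adjusted p = 0.00885, 0.0818 without AID 30 replicate 1). Totals were 2592 genes, 1225 higher and 1367 lower, 501 and 825 by more than 2-fold, and 2653 and 610 by library size alone, where the median of all genes was 0.622. 121 of 138 cytosolic ribosomal protein genes fell and 0 rose (128 and 0 adjusted over the list alone). Their median was -1.34 (adjusted p = 4.01e-17, adjusted p = 0.653 with an estimated correlation). 109 of 123 ribosome biogenesis genes fell and 0 rose (113 and 0 adjusted over the list alone). Their median was -1.47 (adjusted p = 1.85e-37, adjusted p = 0.0842 with an estimated correlation). Histone mRNAs, raised at 10 min, came down: 8 of 8 core histone genes fell and 0 rose (the same adjusted over the list alone), with HTA1 at -2.77 ± 0.37. Their median was -1.84 (adjusted p = 2.32e-06, adjusted p = 0.317 with an estimated correlation). 19 of 28 ergosterol genes fell and 1 rose (20 and 1 adjusted over the list alone). Their median was -0.76 (adjusted p = 2.36e-06, adjusted p = 0.0496 with an estimated correlation). 8 of 18 glycolysis and fermentation genes fell and 0 rose (the same adjusted over the list alone), a call that ended at adjusted p = 0.0782 without AID 10 replicate 1 and 0.149 without AID 30 replicate 2. Their median was -0.63 (adjusted p = 0.0344, adjusted p = 0.722 with an estimated correlation).

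Both arms shared most of their NaCl response. At 10 min 891 genes rose and 744 fell in both arms where 230.8 and 252.6 would under independence, and 11 moved in opposite directions. At 30 min 1382 rose and 1312 fell in both (489.9 and 453.8 under independence), with 13 opposite. The slope of the Xrn1-AID response on the Xrn1-WT response over all genes was 0.979 at 10 min (95% bounds over genes 0.955 to 1.002, jackknife SE over libraries 0.075, r = 0.859). At 30 min it was 0.947 (0.931 to 0.962, jackknife SE 0.061, r = 0.893). Without WT 0 replicate 1 these slopes were 0.933 and 0.91, and without AID 30 replicate 2 the second was 0.992.

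The next comparison asked which mRNAs differed between Xrn1-AID and Xrn1-WT before NaCl. The phospholipase gene ATG15 (YCR068W, chromosome III, 237214 to 238776) went from 4.44 ± 3.67 to 24.7 ± 2.66 CPM (2.48 ± 0.53, adjusted p = 0.00277, n = 3 and 3), and ENT4 (YLL038C, 2.43 ± 0.56) and YDL109C (2.63 ± 0.51) were higher too. Subtelomeric helicase-like frames with near-identical copies, YBL111C (2.99 ± 0.55), YHR218W (2.95 ± 0.49) and YFL066C (2.50 ± 0.56), were also higher, with uncertain counts. Without WT 0 replicate 2 the differences of these 6 were 3.33, 3.15, 3.51, 3.94, 3.82 and 3.37. Lower were the mitochondrial ribosomal RNAs 15S_rRNA (-5.15 ± 1.61, adjusted p = 0.0575 and 0.0618 without WT 0 replicates 1 and 3, 0.0771, 0.0696 and 0.0639 without AID 0 replicates 1, 2 and 3) and 21S_rRNA (-3.69 ± 1.26, adjusted p = 0.0788, 0.0559 and 0.0848 without WT 0 replicates 1, 2 and 3, 0.114, 0.0924 and 0.069 without AID 0 replicates 1, 2 and 3) and the small nucleolar RNA snR190 (-5.10 ± 1.81, adjusted p = 0.133 and 0.092 without WT 0 replicates 1 and 3, 0.11, 0.109 and 0.0926 without AID 0 replicates 1, 2 and 3). Small frames YKL202W (-4.23 ± 0.52), YLR342W-A (-3.33 ± 0.50) and YLR285C-A (-3.33 ± 0.38) were lower as well (YLR342W-A -2.25 without WT 0 replicate 3). A total of 2019 genes passed, 1003 higher and 1016 lower, 402 and 334 by more than 2-fold, and 1331 passed without AID 0 replicate 3. The stress genes STL1 (-3.06 ± 0.73) and HSP12 (-2.96 ± 0.65) were lower in Xrn1-AID at 0 min. Without WT 0 replicate 1 they stood at -1.19 (adjusted p = 0.0407) and -1.08 (adjusted p = 0.0127).

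Lists were also compared between the arms at 0 min. 39 of 123 ribosome biogenesis genes were lower and 1 higher (the same adjusted over the list alone), as in NOP56 (YLR197W, -1.49 ± 0.27) and LOC1 (YFR001W, -1.304 ± 0.17). Their median was -0.30 (adjusted p = 4.14e-06, adjusted p = 0.677 with an estimated correlation). 15 of 138 cytosolic ribosomal protein genes were lower and 1 higher (4 and 0 adjusted over the list alone). Their median was -0.41 (adjusted p = 0.000146, adjusted p = 0.824 with an estimated correlation; median -0.12 without WT 0 replicate 3). 17 of 69 mitochondrial ribosomal protein genes were lower and 0 higher (15 and 0 adjusted over the list alone), with MRPS17 (YMR188C, -1.05 ± 0.15) lowest. Their median was -0.30 (adjusted p = 0.000847, adjusted p = 0.695 with an estimated correlation). 11 of 33 proteasome genes were lower and 0 higher (the same adjusted over the list alone), among them RPN9 (YDR427W, -1.24 ± 0.14). Their median was -0.23 (adjusted p = 0.00353, adjusted p = 0.592 with an estimated correlation). With the drug pump regulon member GTT2 (YLL060C, 1.55 ± 0.19) higher, 6 of 17 pleiotropic drug resistance genes were higher and 1 lower (the same adjusted over the list alone). Their median was 0.48 (adjusted p = 0.0132, adjusted p = 0.657 with an estimated correlation; median 0.27 without WT 0 replicate 3). 8 of 21 cell wall integrity genes were higher and 1 lower (the same adjusted over the list alone). Their median was 0.20 (adjusted p = 0.0184, adjusted p = 0.631 with an estimated correlation; median 0.33 without WT 0 replicate 2, 0.35 without AID 0 replicate 2). In all 5 lists were higher, 4 were lower and 13 did not pass (adjusted p from 0.0726 to 0.833), and 9 of the 9 calls were lost with an estimated correlation. Ended calls were the cell wall integrity genes (adjusted p = 0.45 after the GC and length correction), the cytosolic ribosomal protein genes (adjusted p = 0.216 without WT 0 replicate 3) and the pleiotropic drug resistance genes (adjusted p = 0.067 without AID 0 replicate 1).

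At 10 min of NaCl the arms were compared in the same way. ENT4 (2.70 ± 0.58), GZF3 (YJL110C, 1.86 ± 0.21), POP3 (YNL282W, 1.85 ± 0.38), YIR042C (1.84 ± 0.25), NIT1 (YIL164C, 1.82 ± 0.21) and DAL5 (YJR152W, 1.74 ± 0.21) were highest in Xrn1-AID, where GZF3 is a nitrogen regulator and DAL5 the allantoate permease (chromosome X, 719666 to 721297), at 6.11 ± 1.24 and 20.5 ± 3.62 CPM (adjusted p = 0.000125, n = 3 and 3). Without WT 10 replicate 1 ENT4 stood at 3.34. Lowest were snR190 (-7.44 ± 1.82, -5.75 without WT 10 replicate 2), 15S_rRNA (-5.29 ± 1.39, -6.34 without AID 10 replicate 1, adjusted p = 0.0715 without WT 10 replicate 2, 0.0505 without AID 10 replicate 3), 21S_rRNA (-5.02 ± 1.24, adjusted p = 0.051 without WT 10 replicate 2), the U3 RNA snR17a (-4.09 ± 1.216, adjusted p = 0.105 without WT 10 replicate 2, 0.0752, 0.0656 and 0.0656 without AID 10 replicates 1, 2 and 3), LSR1 (-3.98 ± 1.09, adjusted p = 0.0658 without WT 10 replicate 2, 0.0505 and 0.0564 without AID 10 replicates 2 and 3) and OST5 (YGL226C-A, -3.32 ± 0.61). In total 1749 genes passed, 1072 higher and 677 lower, 276 and 275 by more than 2-fold, and 1031 passed without AID 10 replicate 1. Other scalings gave 835 and 314 (library size alone, median of all genes 0.268) and 846 and 861 (DESeq2 size factors). The compared groups alone gave 730 and 758, and DESeq2 gave 972 and 1055.

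33 of 138 cytosolic ribosomal protein genes were lower and 2 higher (27 and 2 adjusted over the list alone), as in RPP1A (YDL081C, -1.67 ± 0.42), whose call ended without WT 10 replicate 2 (-0.98, adjusted p = 0.0702). Their median was -0.61 (adjusted p = 6.21e-12, adjusted p = 0.695 with an estimated correlation; median -0.23 without WT 10 replicate 2). 10 of 28 ergosterol genes were lower and 0 higher (the same adjusted over the list alone), with IDI1 (YPL117C, -1.11 ± 0.14) and MVD1 (YNR043W, -0.86 ± 0.15) lower. Their median was -0.27 (adjusted p = 3.84e-05, adjusted p = 0.0754 with an estimated correlation). 14 of 47 Msn2/Msn4 general stress genes were higher and 3 lower (18 and 3 adjusted over the list alone), for example RTN2 (YDL204W, 1.28 ± 0.31) and GSY2 (YLR258W, 1.27 ± 0.26). Their median was 0.50 (adjusted p = 0.00665, 0.738 with an estimated correlation). 6 of 27 Hsf1 chaperone genes were lower and 1 higher (the same adjusted over the list alone), BTN2 (-2.26 ± 0.29) and CUR1 (YPR158W, -1.27 ± 0.22) among them. Their median was -0.24 (adjusted p = 0.00728, adjusted p = 0.667 with an estimated correlation; median -0.10 and -0.12 without WT 10 replicates 2 and 3). 15 of 69 mitochondrial ribosomal protein genes were higher and 0 lower (the same adjusted over the list alone). Their median was 0.25 (adjusted p = 0.0277, 0.789 with an estimated correlation, median 0.14 without AID 10 replicate 1). In all 3 lists were higher, 5 were lower and 14 did not pass (adjusted p from 0.0697 to 0.997), and 8 of the 8 calls were lost with an estimated correlation. The mitochondrial ribosomal protein call ended at adjusted p = 0.324 without WT 10 replicate 1, 0.184 without AID 10 replicate 1 and 0.0602 with DESeq2 size factors. The Msn2/Msn4 call ended at 0.151 without WT 10 replicate 1 and 0.0856 after the GC and length correction. The Hsf1 chaperone call ended at 0.0516 without WT 10 replicate 3, that of ribosome biogenesis at 0.941 without WT 10 replicate 1.

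After 30 min of NaCl (n = 3 and 2) the highest genes in Xrn1-AID were YHR218W (1.88 ± 0.51, adjusted p = 0.0605 without WT 30 replicate 3, 0.252 without AID 30 replicate 2), MET1 (YKR069W, 1.87 ± 0.17), YBL111C (1.85 ± 0.58, adjusted p = 0.0637, 0.0809 and 0.0926 without WT 30 replicates 1, 2 and 3, 0.473 without AID 30 replicate 2), the polyamine pump gene TPO2 (YGR138C, 1.84 ± 0.23), ENT4 (1.84 ± 0.59, adjusted p = 0.0693, 0.0915 and 0.0996 without WT 30 replicates 1, 2 and 3, 0.504 without AID 30 replicate 2) and DAL7 (YIR031C, 1.76 ± 0.19). The lowest were snR190 (-6.91 ± 2.05, adjusted p = 0.121 without WT 30 replicate 3, 0.0944 and 0.195 without AID 30 replicates 1 and 2), 21S_rRNA (-4.03 ± 1.39, adjusted p = 0.36 without WT 30 replicate 3, 0.109 and 0.281 without AID 30 replicates 1 and 2), YER053C-A (-3.58 ± 0.65), OST5 (-3.54 ± 0.75, adjusted p = 0.063 without AID 30 replicate 2), HXT2 (-3.18 ± 0.49) and YLR285C-A (-2.58 ± 0.42). Without AID 30 replicate 1 YBL111C and ENT4 stood at 2.44 and 2.43, and YER053C-A, OST5 and HXT2 at -4.18, -4.20 and -3.77. A total of 1393 genes passed, 713 higher and 680 lower, 264 and 303 by more than 2-fold. The total was 518 without AID 30 replicate 2, 913 without AID 30 replicate 1 and 900 without WT 30 replicate 3.

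At 30 min 30 of 138 cytosolic ribosomal protein genes were higher and 0 lower (the same adjusted over the list alone), with RPS28B (YLR264W, 1.33 ± 0.25). Their median was 0.57 (adjusted p = 1.72e-09, adjusted p = 0.701 with an estimated correlation; median 0.37 without AID 30 replicate 1). 33 of 123 ribosome biogenesis genes were higher and 4 lower (40 and 5 adjusted over the list alone). Their median was 0.38 (adjusted p = 4.57e-05, adjusted p = 0.695 with an estimated correlation). 11 of 28 ergosterol genes were lower and 0 higher (the same adjusted over the list alone), among them ERG5 (YMR015C, -1.62 ± 0.28) and ERG13 (YML126C, -1.31 ± 0.23). Their median was -0.46 (adjusted p = 4.31e-07, adjusted p = 0.0493 with an estimated correlation; median -0.31 without WT 30 replicate 1). Decay factors LSM2 (YBL026W, -2.28 ± 0.39), LSM4 (YER112W, -1.76 ± 0.27) and SKI7 (YOR076C, -1.62 ± 0.25) were lower, and of the list 8 of 46 mRNA decay factor genes were lower and 0 higher (the same adjusted over the list alone). Their median was -0.15 (adjusted p = 0.0196, adjusted p = 0.544 with an estimated correlation). 7 of 37 oxidative phosphorylation genes were lower and 0 higher (the same adjusted over the list alone), with ATP20 (YPR020W, -2.24 ± 0.44) lowest. Their median was -0.14 (adjusted p = 0.0308, adjusted p = 0.701 with an estimated correlation; median -0.23 and -0.09 without WT 30 replicates 2 and 3). In all 2 lists were higher, 7 were lower and 13 did not pass (adjusted p from 0.0678 to 0.993), and 8 of the 9 calls were lost with an estimated correlation. Ended calls were the mRNA decay factor genes (adjusted p = 0.105 without AID 30 replicate 1) and the oxidative phosphorylation genes (adjusted p = 0.0587 and 0.126 without WT 30 replicates 1 and 3, 0.0762 without AID 30 replicate 2).

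LSM2 was lower in Xrn1-AID at every time (-2.21 ± 0.33, -2.07 ± 0.33 and -2.28 ± 0.39), and ENT4 was higher at 0 min (2.43 ± 0.56, 3.15 without WT 0 replicate 2) and 10 min (2.70 ± 0.58, 3.34 without WT 10 replicate 1). At all 3 times 259 genes were higher and 236 lower, where 19.98 and 12.19 would be under independence. Correlations over genes between times were 0.761 (0 and 10 min), 0.648 (0 and 30 min) and 0.606 (10 and 30 min). The differences followed the base composition of the coding region: the tenth of genes lowest in GC had medians of -0.634, -0.345 and -0.579 at 0, 10 and 30 min, and the tenth highest in GC 0.31, 0.206 and 0.408. After the correction these medians at 0 min were -0.066 and -0.076, and of the 458 genes it reached 245 remained called the same way at all times.

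The strain carries mutant alleles of HIS3, LEU2, TRP1, ADE2 and CAN1, and their transcripts were higher in Xrn1-AID over the 3 times. The changes were 1.77 ± 0.13 for HIS3 (YOR202W, chromosome XV, 721946 to 722608, adjusted p = 1.44e-07), 1.40 ± 0.08 for ADE2 (YOR128C, chromosome XV, 564476 to 566191, adjusted p = 1.84e-08) and 1.24 ± 0.14 for LEU2 (YCL018W, adjusted p = 5.89e-06). They were 1.224 ± 0.15 for CAN1 (YEL063C, adjusted p = 1.17e-05) and 0.87 ± 0.12 for TRP1 (YDR007W, adjusted p = 3.46e-05), and URA3 (YEL021W), labelled as the OsTIR1 marker at a mutant ura3 allele, did not pass (-0.24 ± 0.10, adjusted p = 0.0516). After the GC and length correction they were 1.46, 1.23, 1.00, 1.01 and 0.77, and URA3 was lower (-0.42 ± 0.08, adjusted p = 0.000361). A HIS marker is labelled at the degron in both arms, and HIS3 counts do not separate that marker from the mutant allele.

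The last 3 comparisons asked whether the NaCl response itself differed between the arms, and few genes passed. Among genes called at 10 min with a mean of at least 10 CPM, the citrate synthase gene CIT2 (YCR005C, 1.42 ± 0.24) had the largest positive difference (2.59 ± 0.18 in Xrn1-AID and 1.17 ± 0.17 in Xrn1-WT, adjusted p = 0.0244), then COG8 (YML071C, 1.21 ± 0.24), THI80 (YOR143C, 1.19 ± 0.22), CEF1 (YMR213W, 1.19 ± 0.25), FAR10 (YLR238W, 1.15 ± 0.24) and ULP1 (YPL020C, 1.14 ± 0.24). The flocculin gene FLO11 (YIR019C, -2.22 ± 0.38) had the largest negative (-1.43 ± 0.27 and 0.79 ± 0.27), then BTN2 (-2.18 ± 0.39), ATG41 (YPL250C, -2.01 ± 0.36), SSA4 (-1.91 ± 0.32), ALG3 (YBL082C, -1.504 ± 0.30) and MIR1 (YJR077C, -1.46 ± 0.29). Panel genes STL1 (3.45 ± 0.93), HSP12 (3.35 ± 0.87), SIP18 (2.54 ± 0.72), GRE1 (1.75 ± 0.59), ALD3 (1.54 ± 0.55) and CTT1 (1.48 ± 0.58) differed by more than CIT2 without passing (adjusted p from 0.0753 to 0.194). STL1 and HSP12 passed without WT 0 replicate 2 or 3 (3.78 to 3.92), SIP18 and ALD3 without 2. Without replicate 1 STL1 and HSP12 rose by 9.92 and 7.41 in Xrn1-WT, nearer Xrn1-AID (11.49 and 8.89). In total 48 genes passed, 18 higher and 30 lower, and 1081 had an unadjusted p below 0.05. No gene passed (edgeR, 0 genes, unadjusted 854 to 986) without any 1 of WT 0 replicate 1, WT 10 replicate 1, AID 0 replicates 2 and 3 or AID 10 replicates 1, 2 and 3. Left-out values were 19 (AID 0 replicate 1), 24 (WT 10 replicate 2), 84 (WT 10 replicate 3), 129 (WT 0 replicate 2) and 137 (WT 0 replicate 3), and each of the 12 named genes lost its call without at least 1 library. Library size alone gave 0 genes in edgeR, with 758 unadjusted and a median of all genes of 0.201, where DESeq2 gave 303 genes with all libraries. After the GC and length correction 35 genes were higher and 18 lower.

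As lists, of 69 mitochondrial ribosomal protein genes 0 were higher and 0 lower (21 and 0 adjusted over the list alone). Their median was 0.54 (adjusted p = 1.59e-13, 0.33 with an estimated correlation). Of 27 Hsf1 chaperone genes 0 were higher and 2 lower (0 and 3 adjusted over the list alone). Their median was -0.41 (adjusted p = 2.4e-08, 0.204 with an estimated correlation). Of 28 Hog1 osmostress effectors 0 were higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 0.49 (adjusted p = 0.00536, 0.695 with an estimated correlation, median 0.24 and 0.75 without WT 0 replicates 1 and 2, 0.33 and 0.76 without WT 10 replicates 1 and 2). In all 5 lists were higher, 8 were lower and 9 did not pass (adjusted p from 0.0891 to 0.975), and 13 of the 13 calls were lost with an estimated correlation. Leaving out 1 library ended the calls of the Hog1 osmostress effectors (adjusted p = 0.143 without WT 0 replicate 1).

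Among genes called at 30 min with that mean, the acid phosphatase genes PHO12 (2.12 ± 0.24) and PHO11 (2.04 ± 0.20), a near-identical pair, had the largest positive differences. Both fell by less in Xrn1-AID (-3.56 ± 0.21 and -5.68 ± 0.19 for PHO12). RPL15A (YLR029C, 2.01 ± 0.43), MHT1 (YLL062C, 1.83 ± 0.27), CBF5 (YLR175W, 1.63 ± 0.25) and HCA4 (1.48 ± 0.26) followed. HSP12 (3.41 ± 0.90), SIP18 (2.25 ± 0.71) and STL1 (2.15 ± 0.96) differed by more than PHO12 without passing (adjusted p = 0.0643, 0.121 and 0.253). HSP12 passed without WT 0 replicate 2 or 3 (3.90, 3.83), SIP18 without 2. Without replicate 1 HSP12 and STL1 rose by 8.415 and 8.72 in Xrn1-WT, nearer Xrn1-AID (9.96 and 9.00). The most negative were MGA1 (-3.17 ± 0.60), SSA4 (-2.70 ± 0.35), RSB1 (-2.15 ± 0.48), YJR115W (-2.03 ± 0.36), HXT6 (YDR343C, -1.95 ± 0.44) and YHR022C (-1.95 ± 0.47), where HXT6 has a near-identical neighbour. MGA1 had risen by 4.67 ± 0.42 in Xrn1-WT and 1.501 ± 0.41 in Xrn1-AID. ENA1 rose less in Xrn1-AID (-1.46 ± 0.32, adjusted p = 0.0373). In total 96 genes passed, 62 higher and 34 lower (1106 unadjusted). Of the genes named here PHO12, PHO11, MHT1 and SSA4 alone kept their calls with each library left out, and against 1.5-fold MHT1 did not pass (adjusted p = 0.0532). Totals were 28, 188 and 57 without WT 0 replicates 1, 2 and 3, 11 and 34 without WT 30 replicates 1 and 3, 20 and 17 without AID 0 replicates 1 and 3, and 6 and 23 without AID 30 replicates 1 and 2. Library size alone gave 17 higher and 1 lower (median of all genes -0.147).

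As lists, of 138 cytosolic ribosomal protein genes 6 were higher and 0 lower (46 and 0 adjusted over the list alone), for example RPL27A (YHR010W, 1.33 ± 0.31) and RPS6A (YPL090C, 1.25 ± 0.30), both with a near-identical copy. Their median was 0.99 (adjusted p = 3.4e-32, adjusted p = 0.441 with an estimated correlation). Of 123 ribosome biogenesis genes 17 were higher and 0 lower (51 and 0 adjusted over the list alone), with UTP23 (1.46 ± 0.25) and RRP8 (YDR083W, 1.40 ± 0.27). Their median was 0.65 (adjusted p = 7.52e-26, 0.175 with an estimated correlation). Of 18 trehalose and glycogen genes 0 were higher and 1 lower (0 and 4 adjusted over the list alone), GSY1 alone passing (-1.59 ± 0.31). Their median was -0.55 (adjusted p = 1.44e-06, 0.294 with an estimated correlation). In all 4 lists were higher, 9 were lower and 9 did not pass (adjusted p from 0.268 to 0.84), and 13 of the 13 calls were lost with an estimated correlation.

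Among genes called between 10 and 30 min with that mean, BTN2 (2.49 ± 0.41), PHO11 (2.26 ± 0.20), ATG41 (2.18 ± 0.39), PHO12 (2.18 ± 0.24), MHT1 (2.11 ± 0.27) and TPO2 (1.98 ± 0.31) had the largest positive differences. The changes of BTN2 were -3.07 ± 0.30 in Xrn1-WT and -0.58 ± 0.31 in Xrn1-AID (adjusted p = 0.0118). The most negative were the transcription factor gene CIN5 (YOR028C, -2.57 ± 0.48), MGA1 (-2.20 ± 0.50), RSB1 (-2.19 ± 0.47), PIG2 (YIL045W, -2.01 ± 0.40), BDH2 (YAL061W, -1.96 ± 0.34) and NRG2 (-1.71 ± 0.26). In total 85 genes passed, 40 higher and 45 lower (1251 unadjusted), and 48 and 33 with DESeq2 size factors. Library size alone gave 39 and 20 and a median of all genes of -0.339. PHO11, PHO12, MHT1 and NRG2 kept their calls with each library left out. Totals were 9, 22 and 237 without WT 10 replicates 1, 2 and 3, 18, 38 and 23 without WT 30 replicates 1, 2 and 3, 14 and 8 without AID 10 replicates 2 and 3, and 7 and 17 without AID 30 replicates 1 and 2. Of 138 cytosolic ribosomal protein genes 9 were higher and 0 lower (103 and 0 adjusted over the list alone). Their median was 1.13 (adjusted p = 6.23e-47, 0.296 with an estimated correlation). In all 5 lists were higher, 6 were lower and 11 did not pass (adjusted p from 0.0888 to 0.993), and 11 of the 11 calls were lost with an estimated correlation.

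**Figure D1:**
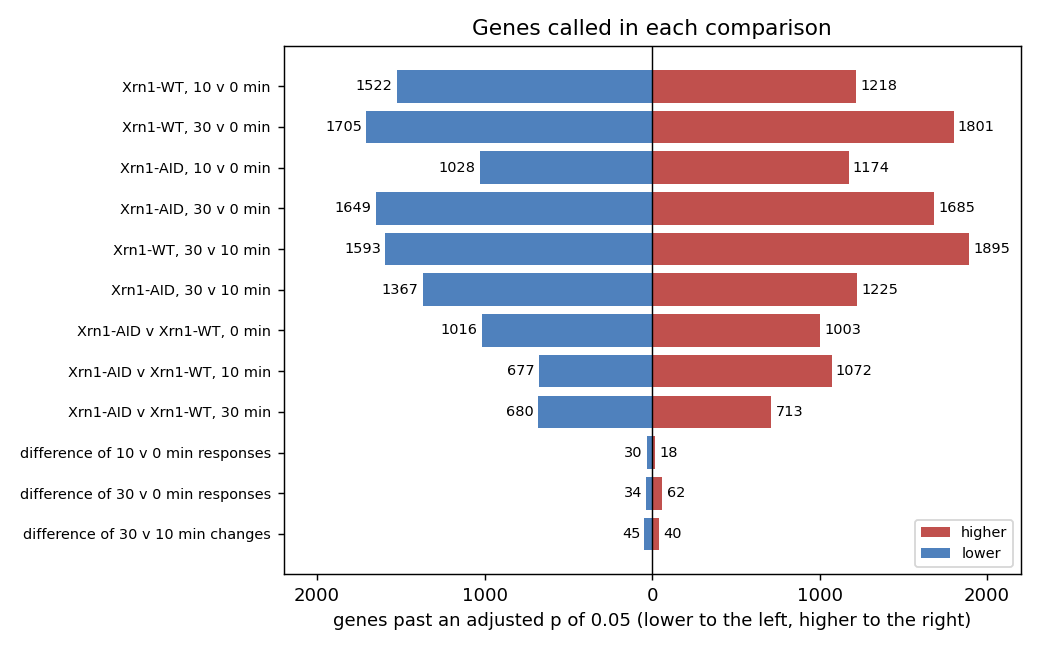
Number of genes called higher and lower in each of the 12 comparisons. The bars reach 1801 and 1705 genes for 30 min of NaCl in Xrn1-WT and 18 and 30 genes for the difference between the 10 min responses.

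**Figure D2:**
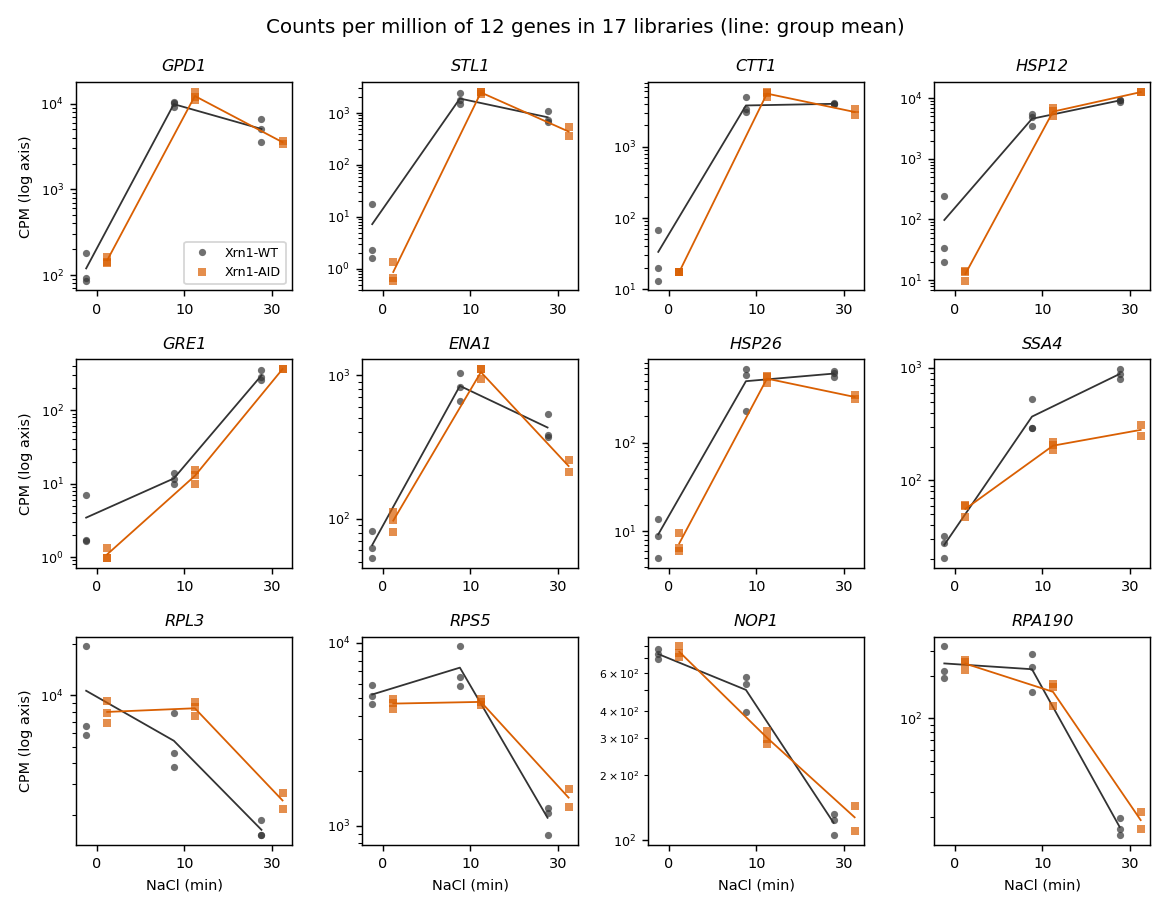
CPM on a log axis of 12 genes in the 17 libraries by arm and time, with lines at group means. STL1 has its highest level at 10 min in both arms, and HSP12 stays high at 30 min.

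**Figure D3:**
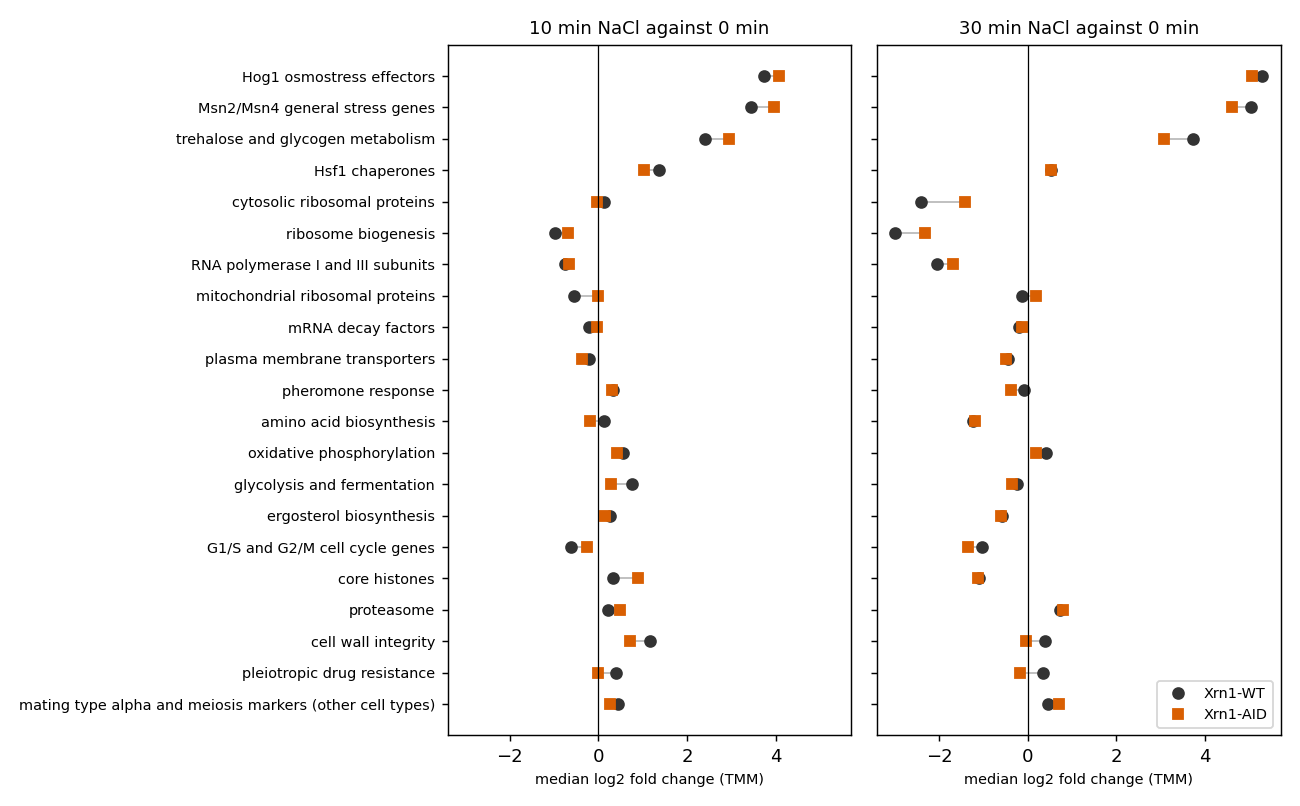
Median log2 change of 21 gene lists at 10 and 30 min of NaCl in Xrn1-WT and Xrn1-AID. Cytosolic ribosomal protein genes stand at -2.41 and -1.42 at 30 min, and the proteasome (median 0.21 at 10 min in Xrn1-WT, -0.23 by library size alone) depends on the scaling.

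**Figure D4:**
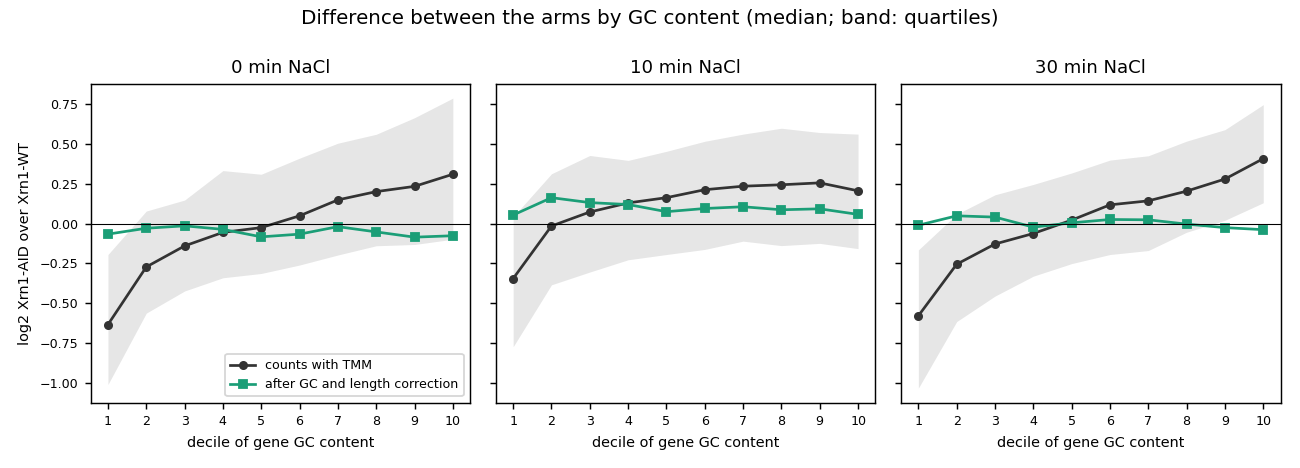
Median log2 difference of Xrn1-AID to Xrn1-WT for genes in 10 classes of GC content, before and after the GC and length correction, with quartiles as bands. The lowest class stands at -0.634 and the highest at 0.31 before NaCl.

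**Figure D5:**
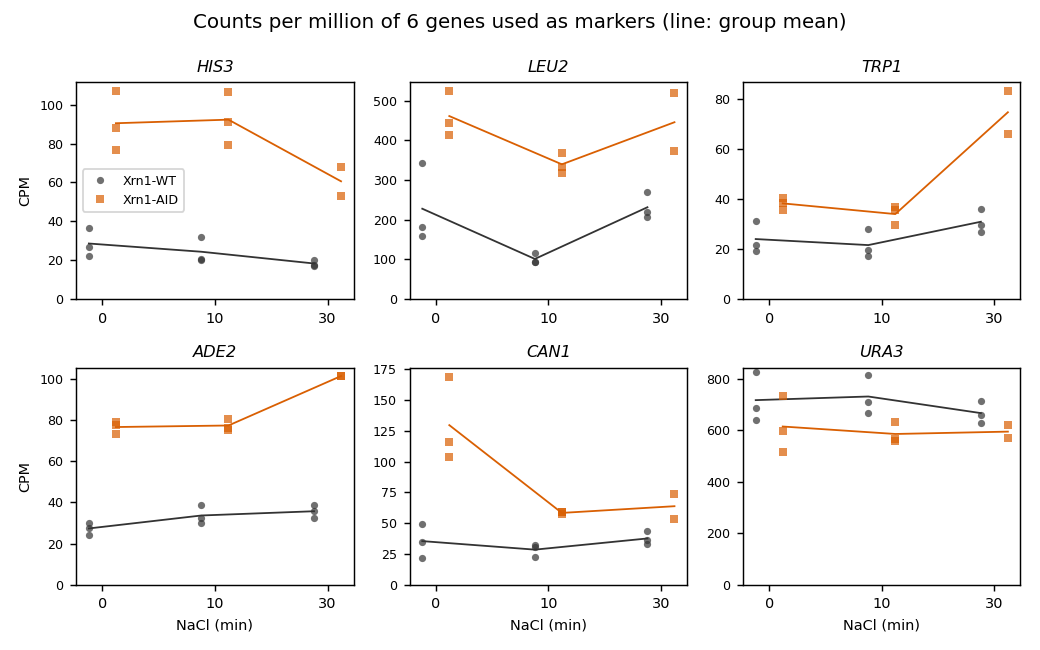
CPM of HIS3, LEU2, TRP1, ADE2, CAN1 and URA3 in the 17 libraries by arm and time. The mutant alleles are higher in Xrn1-AID, by 1.77 for HIS3 over all times, and URA3 is not (-0.24).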

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

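Tests on the GC and coding length trend of the arm difference, on library preparation and on RNA from NaCl-treated cells were chosen after the results were seen. A difference between the arms in the response to NaCl, tested as an interaction, set apart 48 genes at 10 min, 96 at 30 min and 85 between 10 and 30 min (n = 3 per group, 2 for Xrn1-AID at 30 min). Time after auxin rose with NaCl time in Xrn1-AID, so the effects of longer depletion and of NaCl cannot be told apart here. Left-out libraries moved these counts to between 0 (edgeR, 854 to 986 unadjusted) and 137, 6 and 188, and 7 and 237, with the values per library given beside the comparisons. At 10 min the genes were CIT2 (1.42), COG8 (1.21), THI80 (1.19), CEF1 (1.19), FAR10 (1.15) and ULP1 (1.14), against FLO11 (-2.22), BTN2 (-2.18), ATG41 (-2.01), SSA4 (-1.91), ALG3 (-1.504) and MIR1 (-1.46). At 30 min they were PHO12 (2.12), PHO11 (2.04), RPL15A (2.01), MHT1 (1.83), CBF5 (1.63) and HCA4 (1.48), against MGA1 (-3.17), SSA4 (-2.70), RSB1 (-2.15), YJR115W (-2.03), HXT6 (-1.95), YHR022C (-1.95) and ENA1 (-1.46). Between 10 and 30 min they were BTN2 (2.49), PHO11 (2.26), ATG41 (2.18), PHO12 (2.18), MHT1 (2.11) and TPO2 (1.98), against CIN5 (-2.57), MGA1 (-2.20), RSB1 (-2.19), PIG2 (-2.01), BDH2 (-1.96) and NRG2 (-1.71).

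Lists differed too, given as median log2 differences, with those that changed sign or moved by over 1.5 times without 1 library (r for replicate) in parentheses. At 10 min they were Hog1 effectors 0.49 (0.24 and 0.75 without WT 0 r1 and 2, 0.33 and 0.76 without WT 10 r1 and 2), Msn2/Msn4 genes 0.42 (0.23 without WT 0 r1, 0.28 without WT 10 r1), Hsf1 chaperones -0.41, ribosomal proteins -0.12 (-0.05, 0.02 and -0.40 without WT 0 r1, 2 and 3, -0.23, 0.23 and -0.26 without WT 10 r1, 2 and 3, -0.20 and -0.03 without AID 0 r1 and 2), ribosome biogenesis 0.27, mitochondrial ribosomal proteins 0.54, transporters -0.31, amino acid synthesis -0.24 (-0.12 without WT 10 r2), glycolysis -0.49 (-0.25 without WT 10 r2), ergosterol -0.18 (-0.12 without WT 0 r1, -0.12 without WT 10 r2), histones 0.53 (0.80 without WT 10 r2), cell wall -0.35 (-0.53 without WT 0 r2) and drug resistance -0.44 (-0.24 without WT 10 r1, -0.26 without AID 0 r1). At 30 min they were Msn2/Msn4 genes -0.41 (-0.26 and -0.27 without WT 0 r2 and 3), trehalose and glycogen -0.55, ribosomal proteins 0.99, ribosome biogenesis 0.65, RNA polymerases I and III 0.36, mitochondrial ribosomal proteins 0.23, transporters -0.23 (-0.14 and -0.35 without AID 0 r1 and 2), oxidative phosphorylation -0.23 (-0.13 and -0.41 without WT 30 r1 and 2, -0.35 and -0.12 without AID 30 r1 and 2), glycolysis -0.18 (-0.01, 0.01 and -0.46 without WT 0 r1, 2 and 3, -0.04 and -0.35 without WT 30 r1 and 2, -0.27 and -0.08 without AID 0 r1 and 2, -0.50 and 0.13 without AID 30 r1 and 2), ergosterol -0.36 (-0.24 without WT 30 r1, -0.21 without AID 30 r2), cell cycle -0.20 (-0.37 and -0.07 without WT 0 r2 and 3, -0.36 without AID 30 r2), cell wall -0.41 and drug resistance -0.60 (-0.35 without AID 0 r1). Between 10 and 30 min they were Hog1 effectors -0.76, Msn2/Msn4 genes -0.67, trehalose and glycogen -0.78, Hsf1 chaperones 0.32, ribosomal proteins 1.13, ribosome biogenesis 0.46 (0.30 without WT 10 r1), RNA polymerases I and III 0.35, mitochondrial ribosomal proteins -0.30 (-0.20 without AID 10 r1), amino acid synthesis 0.24 (0.15 without AID 30 r1, -0.004 with library size alone), cell cycle -0.49 and histones -0.59. With an estimated correlation none of them passed (adjusted p from 0.204 to 0.883 at 10 min, 0.136 to 0.738 at 30 min and 0.205 to 0.744 between them).

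For the 48 genes at 10 min, 2 of 100 regroupings of the arms within each time gave as many. Mixing the arms widens the spread, so this leaves a random grouping open. The other regrouping gave 416 genes, which points to a structure of the samples besides the arms. It set WT 0 replicates 1 and 3, WT 10 replicates 1 and 3, AID 0 replicate 2 and AID 10 replicate 2 against the rest. WT 0 replicate 2 and WT 10 replicate 2, which it moved, had opposite length trends (0.611 and -0.876).

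The 495 genes that differed between the arms in the same direction at all 3 times were matched by 1 of 100 regroupings, the real one (highest other 0 in edgeR), which excludes a random grouping. Without the GC and coding length trends 53.5% of the 458 that the correction reached remained, so these trends are not the whole cause. Libraries of the arms differed in their GC trend by 0.852 on average (0.963, 0.521 and 1.071 at 0, 10 and 30 min, SD within groups 0.289, two-sided exact permutation p = 5e-04, 4000 regroupings). If the arms were prepared apart, preparation and Xrn1 depletion cannot be told apart for the genes that follow the trend. Auxin itself and Xrn1 depletion also stay open, since no auxin-treated cells without a degron were sampled.

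For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each, gave 2740 genes for 10 min in Xrn1-WT (highest other 110), 3506 for 30 min (0), 2202 for 10 min in Xrn1-AID (3), 3488 between 10 and 30 min in Xrn1-WT (0), 2019 for the arms at 0 min (0) and 1749 at 10 min (0), all by edgeR.

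NaCl-induced genes were raised in WT 0 replicate 1 without NaCl. HSP12 stood there at 240.7 CPM against 19.8 and 33.7 in the other replicates, and CTT1 at 67.4 against 13.1 and 20.03. A small share of RNA from NaCl-treated cells could raise them: 79 genes needed a median share of 1.53% of 30 min RNA, but upper and lower quartile (2.18% and 1.07%) differed by 2.03 times, which leaves this open. A stress of the culture before NaCl was tested by genes that peak at 10 and at 30 min, whose median shares (1.86% and 1.55%, quartiles 0.647% to 4.04% and 0.915% to 2.37%) differed by 1.21 times (bounds 1.03 to 1.9, added after the ratio was seen), below the 2 times set beforehand for it. A stress with the gene profile of 30 min NaCl stays open.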

How the results depend on the processing

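The GC and length correction and the omission of the 2 most deviant libraries (WT 0 replicate 3 and WT 10 replicate 2) were chosen after the data were seen, and where no cause is given the cause was not tested. Over all alternatives the named genes gave 16570 values with the same direction and side of the threshold, 1779 that no longer passed, 117 that newly passed and 6 of opposite sign. Of the list tests, not run with library size alone, 3097 stayed on their side of the threshold, 248 no longer passed, 87 newly passed and 0 passed in the opposite direction. Some list medians did change sign, as for ribosome biogenesis between the arms at 10 min (-0.12, 0.02 without WT 10 replicate 1).

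The 6 of opposite sign came with library size alone, which moves every gene alike: URA3 at 10 min (-0.40), 30 min (0.35) and between them (0.75) in Xrn1-WT, QCR8 (0.063) and HIS3 (0.492) between 10 and 30 min in Xrn1-WT, and TPS1 (0.011) in Xrn1-AID. Library size alone gave 1113, 1149 and 724 genes between the arms at 0, 10 and 30 min, and 0 (758 unadjusted) and 18 for the difference in response at 10 and 30 min. A fit of the compared groups alone, with fewer libraries to estimate the spread, gave 1783 genes for 10 min in Xrn1-WT, 1197 for the arms at 0 min, and 19, 8 and 43 for the 3 differences in response. Tested against 1.5-fold, a stricter null, the counts were 1152 and 2209 in Xrn1-WT at 10 and 30 min, 862 and 2000 in Xrn1-AID, 1926 and 1203 between 10 and 30 min, 478, 221 and 210 between the arms, and 0 (edgeR, 253 unadjusted), 3 and 8 for the differences in response.

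The differences in response moved most. DESeq2 gave 303, 337 and 477 genes, the omission of the 2 deviant libraries 73, 174 and 180, and the GC and length correction 175 at 30 min and 349 between 10 and 30 min. A block by the replicate number of the descriptions gave 0 (edgeR, 933 unadjusted), 27 and 13, and by that of the titles 8 at 30 min and 12 between 10 and 30 min. Libraries of the same number had a median residual correlation of -0.0535 (10 of 40 pairs above 0.1), and 2 of 17 matched their own number best. Residuals sum to 0 in a group, so pairing stays open.

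Left-out libraries gave 2420 to 2904 and 3173 to 3510 genes in Xrn1-WT at 10 and 30 min, 1724 to 1879 and 2773 to 3125 in Xrn1-AID, 3097 to 3330 and 1974 to 2466 between 10 and 30 min, 1331 to 2427, 1031 to 1663 and 518 to 1066 between the arms, and 0 (edgeR, 854 to 986 unadjusted) to 137, 6 to 188 and 7 to 237 for the differences. Where AID 30 keeps 1 library, that lone sample is assumed to vary like the other groups.

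With an estimated correlation 3 and 5 lists passed in Xrn1-WT at 10 and 30 min, 3 and 5 in Xrn1-AID and 2 and 2 between 10 and 30 min. Fry does not compare a list with other genes. It gave 17 lists for 30 min in Xrn1-WT and 3 and 5 for the arms at 10 and 30 min. For the differences it gave 3, 5 and 6. Slopes were 0.841 and 0.846 by ordinary regression, which noise in the Xrn1-WT values lowers, and 0.933 to 1.003 and 0.91 to 0.992 with libraries left out. Depth set the floor at 0.104 to 0.279 CPM. The 14.9% of simulated 1.5-fold changes recovered at 10 min in Xrn1-WT covers means of at least 10 CPM, not genes near the floor.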

Other observations

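Groups of genes described here, and the tests on GC content and the HIS marker, were chosen after the data were seen. In a group of phosphate genes that also held the kinetochore gene CTF19 (YPL018W, -1.64 ± 0.52 and -2.15 ± 0.59 at 30 min), 14 of 15 were lower after 30 min of NaCl in Xrn1-WT (median -2.35) and 14 of 15 in Xrn1-AID (median -1.99). Among them were the acid phosphatase gene PHO5 (YBR093C, -4.10 ± 0.22 and -2.86 ± 0.24), the polyphosphate synthesis gene VTC3 (YPL019C, -2.76 ± 0.14 and -1.99 ± 0.16) and SPL2 (YHR136C, -2.73 ± 0.24 and -2.16 ± 0.28). At 30 min in Xrn1-WT the heme oxygenase gene HMX1 (YLR205C) rose (3.83 ± 0.15) and the reductase gene FRE1 (YLR214W) fell (-4.26 ± 0.22), with 12 of 19 iron genes higher and 2 lower. Of 23 sulfate assimilation and methionine genes 18 were lower and 2 higher at 30 min in Xrn1-WT (median -1.23) and 14 and 1 in Xrn1-AID (median -0.71), with 4 higher and 0 lower in the difference. Of 24 poor nitrogen source genes 11 were higher and 1 lower in Xrn1-AID at 0 min (median 0.54, 0.227 after the GC and length correction). The 16 not named before did not pass as a group (adjusted p = 0.158), and DUR3 (YHL016C) and GAP1 (YKR039W) stood at 1.24 ± 0.19 and 0.58 ± 0.14.

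Of 299 tested frames outside the RefSeq annotation, mostly dubious or overlapping ones, 35 were higher and 76 lower in Xrn1-AID at 0 min (median -0.335) and 13 and 64 at 10 min (median -0.606), against 37 and 24 at 30 min (median 0.177). Protein-coding genes of RefSeq had medians of -0.007, 0.126 and 0.045. The strand setting is not stated, so these frames may hold counts of genes they overlap, which was not tested. Preparation of the arms stays open too. The GC trend difference kept its sign at 30 min (1.071). The median of the shortest of 10 length classes did not (-0.348, -0.097 and 0.162 over time).

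A hypothesis is that mRNAs with early stop codons, which nonsense-mediated decay passes to Xrn1, were kept when Xrn1 was depleted, and that this may be why the mutant alleles of HIS3, LEU2, TRP1, ADE2 and CAN1 were higher. The test, thought of after the data were seen but set before its own result was, used 24 other transcripts, 14 decay targets from a short list written from memory and 10 annotated pseudogenes, with a median difference of 0.501 over the 3 times (13 higher and 0 lower by edgeR). The GC and length correction does not reach pseudogenes. The 14 decay targets stood at 0.564 before it (8 higher) and 0.748 after it (95% bootstrap bounds 0.284 to 0.997, 12 higher and 0 lower), among them EST1 (YLR233C, 0.63 and 0.91) and TEN1 (YLR010C, 0.79 and 1.35). GC and length trends as the cause are opposed by the correction, which left 81.7% of the alleles' median (1.24 to 1.01). A HIS marker in 1 arm would raise HIS3 alone, but 4 of the 4 other alleles were higher. Auxin as such and library preparation stay open.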
